A study of Mus musculus with 4 samples.

How the data were processed

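Single-cell RNA was measured in 4 libraries of mouse dorsal dura. Per the labels' protocols, the tissue of 4 PBS-perfused wild-type C57Bl/6J mice was pooled for each library, digested with collagenase VIII and DNase I, sorted as DAPI-negative singlets, and made into libraries with version 3 of the Chromium Single Cell 3' chemistry. Replicate 1 came from females of 14.2 months, replicate 2 from males of 9.1 months, and replicates 3 and 4 from females of 2.4 and 2.1 months, with target numbers of 8000, 8000, 10000 and 8000 cells per the labels. The deposited matrices hold counts of UMIs per gene and barcode, made by the authors with Cell Ranger 3.0.1 per the file headers and with mm10 as the genome per the submitters' processing notes; the release of the gene annotation is not given in the sources used here. Each matrix lists 31053 genes and 6794880 barcodes, every barcode the chemistry allows, so that cells had to be called. The 4 matrices held 57762713, 51847085, 75897224 and 87602339 UMIs. Genes are given by symbol, and positions below are on mm10 from GENCODE M21, which held 30934 of the 31053 genes and 200 of the 201 named ones.

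Cells had at least 1000 UMIs and 500 genes and at most 10% of UMIs from mitochondrial genes. Of 6002, 6656, 7763 and 9072 barcodes past the first pair of limits, 16.8%, 13.6%, 29.2% and 28.6% exceeded the mitochondrial limit. Doublets were scored in each library against simulated pairs of cells, and the share expected at 0.8% per 1000 cells was removed, 3.99%, 4.59%, 4.40% and 5.17%. The kept cells held 172529625 UMIs. Free RNA was summed over barcodes of 10 to 200 UMIs, which held 15.5%, 15.4%, 11.4% and 8.37% of all UMIs; the upper bound was raised from 100 after the count distributions were seen. A class level at or below 10% of the free RNA level, in the higher age group, is called a level that free RNA could supply. A check for copied libraries gave a chi-square per degree of freedom of 83.7 between replicates 1 and 2 and 263 between 3 and 4, where sampling alone gives 1.

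Counts were scaled per cell and log-transformed; 2000 variable genes, 40 principal components, 20 neighbours and Leiden clustering at resolution 1 gave the clusters (scikit-learn 1.9.0, leidenalg 0.10.2, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3 under Python 3.11.15; figures with matplotlib 3.10.9). Genes of the fixed lists other than cell type markers were left out of clustering, with mitochondrial and ribosomal genes, Xist and Y-linked genes. A cluster took the name of the class with the highest mean log2 fold of its markers (at least 0.5, fold prior 5 CPM), with at least 3 markers detected in 20% of its cells, unless its 10 leading genes held more markers of another class. Class names stand for cells like those named. Markers, gene lists, comparisons, tests, the rule for named genes and most alternatives were fixed before the data were examined.

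Counts were summed per library and class and tested with edgeR 4.0.16 (quasi-likelihood, filterByExpr, TMM, Benjamini-Hochberg at 0.05) under R 4.3.3. Age was tested as 9 or 14 months against 2 months, 2 libraries on each side, in the 10 classes with at least 50 cells in every library, each class fitted on its own. No covariate was fitted. Only replicate 2 is male, so a sex term would take up that library and leave age to replicate 1 against replicates 3 and 4, the libraries of the fit without replicate 2. Every class was tested against the mean of the others in the 20 classes with at least 20 cells in at least 3 libraries, and the difference of the age effect was tested for each pair of T cells, macrophages and neutrophils, the 3 classes with the most cells in their smallest library; both fits held the library as a block. Gene lists with at least 5 genes tested were compared with camera in limma 3.58.1 at a correlation of 0.01 between genes, and again with an estimated correlation, over 167 lists and classes. With an estimated correlation the test rests on the few residual degrees of freedom of 2 against 2 libraries. It has little power there, and a list that does not pass is not shown to be unmoved. A pass at 0.01 depends on that fixed value. Shares were tested with edgeR on cell numbers, with an exact two-sided permutation p beside it that cannot be under 0.333. A count over the list alone adjusts within the list. Unnamed clusters were not tested.

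Named genes follow a rule. With age, they are the 10 largest rises and 10 largest falls in each of the 3 main classes, and 3 of each in the other classes, among genes called, with at least 20 CPM in the higher group and both older libraries on the same side of both 2-month ones; Xist, Tsix, Y-linked genes and genes known by a clone or model number only were left out. By class, they are the 4 list genes with the largest fold among those called, at 50 CPM or more and highest in that class. Of each list called, up to 4 members with the smallest adjusted p were open to naming. The genes shown here lie at these positions: Gzmk (ENSMUSG00000042385) on chromosome 13 from 113171608 to 113225908, Cd163l1 (ENSMUSG00000025461) on 7 from 140218267 to 140231145, Cxcl13 (ENSMUSG00000023078) on 5 from 95956951 to 95961068, Retnla (ENSMUSG00000061100) on 16 from 48842551 to 48844461, Irf7 (ENSMUSG00000025498) on 7 from 141262706 to 141266481, Tcf21 (ENSMUSG00000045680) on 10 from 22817281 to 22820174 and Ptgs2 (ENSMUSG00000032487) on 1 from 150100031 to 150108227.

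The fits were tested on simulated data with 200 changed genes each, drawn with the depth of the real classes. The age simulations also used the spread of each gene in the real class. Those of the difference between T cells and macrophages and of T cells against the other classes used a fixed spread for all genes. Their recoveries need not hold at the real spread. The age test in T cells recovered 94.9% of 4-fold changes (98 genes) and 52.6% of 2-fold changes (97 genes), with 23 false among 167 calls over 9941 genes; in macrophages 98.0% (99 genes) and 61.0% (100 genes), with 12 of 170 false over 10580 genes; and in neutrophils 75.5% (98 genes) and 18.2% (99 genes), with 6 of 98 false over 8556 genes. In the other 7 classes 85.0% to 97.0% of 4-fold and 19.6% to 61.6% of 2-fold changes were recovered. For the difference between T cells and macrophages 42.0% of 4-fold and 1.00% of 2-fold changes were recovered (100 genes each), with 2 of 45 calls false over 10665 genes, and for T cells against the other classes 94.1% of 4-fold (51 genes) and 52.4% of 2-fold changes (42 genes), with 4 of 74 false over 12781 genes. The smallest class sums behind the age tests were 435252 UMIs for fibroblasts (62 cells, replicate 2) and 469038 for natural killer cells (124 cells, replicate 2), and a single UMI is 2.30 CPM in the former. A cluster with no cell in any library would have a share below 0.0138%.

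Alternatives were run 1 at a time: other count minimums (500 UMIs and 300 genes, or 2000 and 1000), mitochondrial limits of 5% and 20%, doublets kept, a resolution 2 times as high, list genes kept in clustering, DESeq2 1.42.0 in place of edgeR, RLE scaling, no filter on low counts, no genes that free RNA could supply, equal cell numbers per library, the largest cluster of a class alone, unnamed clusters with fibroblast markers counted as fibroblasts, other offsets for shares, no library block, and each library left out. The limit of 20%, the largest cluster alone and the counting of unnamed clusters were added after the data were seen. In fits without 1 library the lone remaining library of an age is assumed to vary like the other group.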

Results

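Single cells were profiled from the dorsal dura, the fibrous outer membrane that lines the skull, in 4 libraries of wild-type C57Bl/6J mice. Each library was a pool of 4 mice. Replicate 1 held tissue from females of 14 months, replicate 2 from males of 9 months, and replicates 3 and 4 from females of 2 months. Xist, the RNA that silences an X chromosome in female cells, was at 1283, 0.272, 1506 and 1580 CPM (counts scaled to a common total) in replicates 1 to 4. The Y-linked helicase gene Ddx3y was at 0, 82.4, 0 and 0, as the labelled sexes require. After filtering, 4794, 5484, 5258 and 6140 cells were kept, with a median of 5166.5, 3552, 6258 and 6619 unique molecular identifiers (UMIs) each. In the 2-month libraries 29.2% and 28.6% of barcodes past the count minimum exceeded 10% mitochondrial UMIs, against 16.8% and 13.6% in the older ones. The labels state no question beyond the profile of the tissue, so the cell classes were compared with each other, and the libraries of 9 and 14 months were compared with those of 2 months. Age goes together with library in the second comparison, and replicate 2 is also the only male library.

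Immune cells made up most of the tissue. Neutrophils held 17.8% of the cells (SD 9.36, n = 4 libraries), macrophages 10.9% (SD 2.54), T cells 10.9% (SD 3.72), conventional dendritic cells 6.64% (SD 1.75) and type 2 innate lymphoid cells 5.92% (SD 2.44). B cells were at 5.39% (SD 3.73) and monocytes 4.84% (SD 1.95). Among stromal and vascular classes, fibroblasts held 6.23% (SD 6.34), blood endothelial cells 5.13% (SD 1.76), pericytes 0.991% (SD 0.213) and Schwann cells 0.532% (SD 0.188). B cell progenitors, at 1.47% (SD 1.11), and myeloid progenitors, at 3.87% (SD 2.15), were also present, as were osteoblasts at 0.453% (SD 0.316). Pinealocytes and choroid plexus or ependymal cells, which belong to the pineal gland and the ventricles, held 1.14% (SD 0.288) and 1.00% (SD 1.11). Of 47 clusters, 39 were named in 21 classes. The unnamed clusters held 11.2% of cells, with a mean of 6.05% in the older libraries and 15.6% at 2 months. The cells were sorted as viable singlets after enzymatic digestion, and these shares are those of the sorted suspension.

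**Figure D1:**
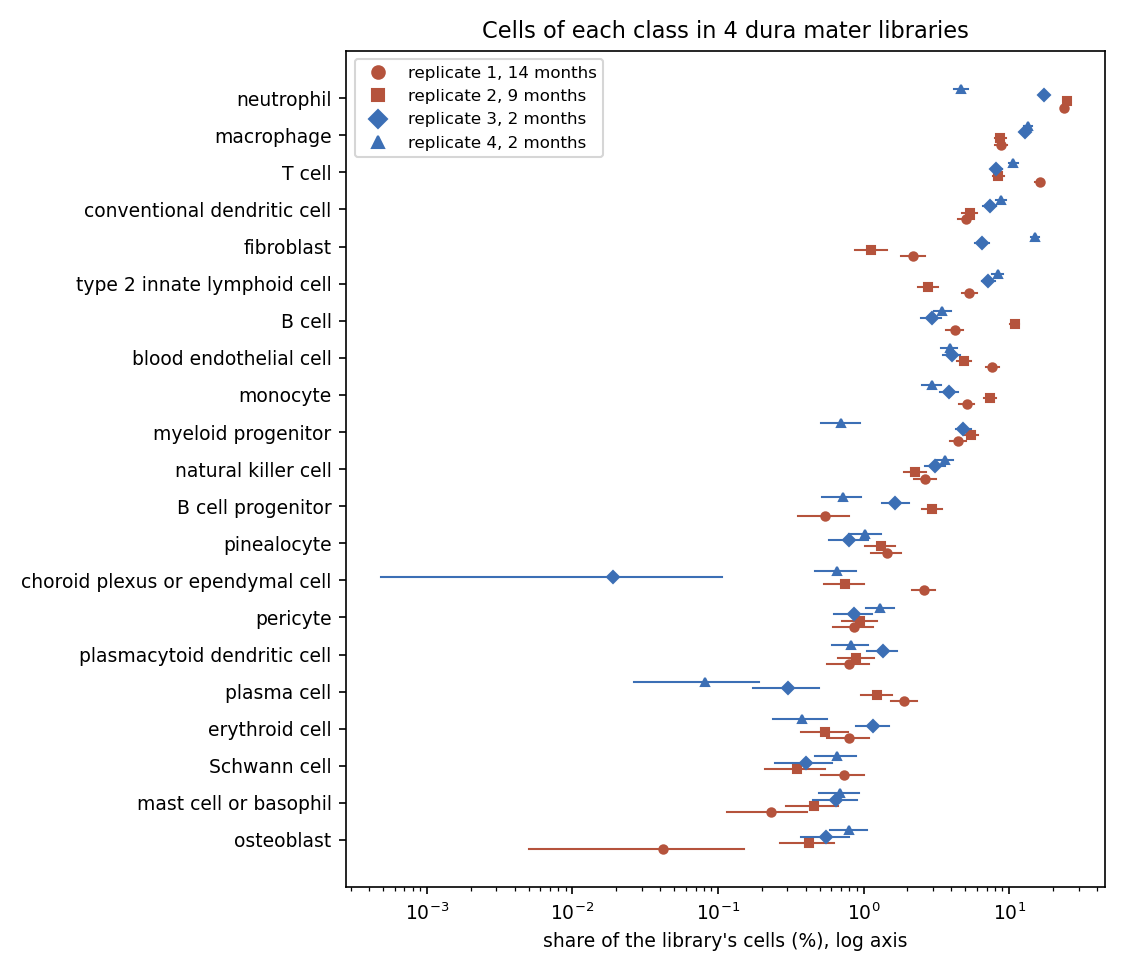
Share of each cell class in each library, in percent of kept cells on a log axis. Each point is 1 library with its exact 95% interval, red for 9 or 14 months and blue for 2 months. Fibroblasts had a mean of 1.66% in the older libraries and 10.8% at 2 months, plasma cells 1.57% and 0.193%.

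Among the named classes, plasma cells and fibroblasts had the largest log2 ratios between the ages. Fibroblasts, which lay down the collagen of the dura, held 2.19% and 1.13% of cells in the older libraries and 6.52% and 15.1% at 2 months (log2 ratio −2.70, SE 0.67, adjusted p 0.183, edgeR). Plasma cells, which secrete antibody, held 1.90% and 1.24% in the older libraries and 0.304% and 0.0814% at 2 months (3.03, SE 0.77, adjusted p 0.183). In replicates 1 to 4 neutrophils held 23.9%, 25.1%, 17.4% and 4.67% (1.15, SE 0.74, adjusted p 0.349), with a log2 ratio of 2.39 and 0.49 without replicates 3 and 4 and of 0.67 with 5% as the mitochondrial limit. B cells held 4.23%, 10.9%, 2.93% and 3.47% (1.24, SE 0.60, adjusted p 0.349), with 0.40 without replicate 2 and 1.89 with that limit. Type 2 innate lymphoid cells held 5.34%, 2.77%, 7.21% and 8.36% (−0.94, SE 0.48, adjusted p 0.349), with −1.49 and −0.54 without replicates 1 and 2. With edgeR 0 of the 21 classes passed and 2 had an unadjusted p under 0.05. The exact two-sided permutation p of fibroblasts and plasma cells was 0.333, the smallest that 2 against 2 libraries can give. When shares were taken among immune cells alone, plasma cells passed (2.78, adjusted p 0.0202, the only one of that set to do so).

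Genes of transporters and vascular signals separated the vessel, barrier and glial classes. Blood endothelial cells had the highest level of Slco1a4, an organic anion transporter of brain vessels, at 432 CPM (SD 282, n = 4 libraries; log2 fold against the other classes 8.75, SE 0.21). They also led in the Notch ligand gene Dll4, at 106 CPM (SD 25.4; 8.93, SE 0.26). Pericytes led in Abcc9, a subunit of ATP-sensitive potassium channels, at 1332 CPM (SD 354; 11.01, SE 0.18). Choroid plexus or ependymal cells led in the bicarbonate transporter Slc4a5 (138 CPM, SD 47.2, n = 3 libraries) and the thyroid hormone transporter Slco1c1 (242 CPM, SD 65.8). Schwann cells led in Abca8a (903 CPM, SD 302, n = 3 libraries), in Dhh, the hedgehog ligand of these cells (115 CPM, SD 56.5), and in Col28a1 (log2 fold 9.96, SE 0.43). Fibroblasts led in Slc47a1 (415 CPM, SD 163) and Slc26a7 (393 CPM, SD 54.0). Mast cells or basophils led in the serotonin transporter Slc6a4 (250.2 CPM, SD 53.8, n = 3 libraries) and pinealocytes in the vesicular glutamate transporter Slc17a6 (191.5 CPM, SD 45.3). Of 235 solute carriers tested, 131 were called and highest in 1 class with at least 50 CPM there, led by pinealocytes (17), choroid plexus or ependymal cells (16), fibroblasts (15) and osteoblasts (13). So were 25 of 36 ABC transporters, led by blood endothelial cells (5). Col28a1 and Slc4a5 did not pass with DESeq2 in place of edgeR.

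Chemokines, cytokines and their receptors marked the immune classes and their neighbours. Conventional dendritic cells led in Ccl17 (281 CPM, SD 169; log2 fold 9.83, SE 0.24) and Ccl22 (94.5 CPM, SD 73.0), both ligands of Ccr4. They led too in Xcr1, the receptor of cross-presenting cells (162 CPM, SD 24.4). Natural killer cells led in Xcl1, the ligand of Xcr1 (1009 CPM, SD 249; 8.44, SE 0.18), and in Ifng (76.2 CPM, SD 11.3). Macrophages led in the monocyte attractant Ccl12 (253 CPM, SD 35.9), in Ccl8 (422 CPM, SD 209) and in the lipid receptor Trem2 (302.5 CPM, SD 41.8). Monocytes led in Ccr2, the receptor of Ccl12 (1328 CPM, SD 189). T cells led in Cxcr6 (526 CPM, SD 192), Cxcr3 (191.5 CPM, SD 35.9) and Il18r1 (283 CPM, SD 91.6). B cells led in Cxcr5, the follicle homing receptor (77.8 CPM, SD 9.52). The alarmin gene Il33 was highest in fibroblasts (263 CPM, SD 53.3; 7.86, SE 0.18). Type 2 innate lymphoid cells led in the cytokine receptor genes Il2ra (386 CPM, SD 53.4) and Il9r (70.2 CPM, SD 9.04). They led as well in the osteoclast cytokine gene Tnfsf11 (71.7 CPM, SD 15.3) and Vipr2, a receptor of vasoactive intestinal peptide (52.8 CPM, SD 14.9). Mast cells or basophils led in the degranulation receptor Mrgprb2 (287 CPM, SD 193, n = 3 libraries). By the same count 23 of 27 chemokines tested were called and highest in 1 class, and 59 of 78 chemokine and cytokine receptors, beside 768 of all 981 list genes. Of 46 receptors of neuropeptides, amines, purines and irritants 32 were, led by mast cells or basophils (6) and blood endothelial cells (5). Of 33 interleukins and other cytokines tested, neutrophils held the most (5). A gene counted for 1 class could be called higher in other classes too.

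Matrix, antigen presentation, interferon-stimulated and cell cycle genes were unevenly spread over the classes too. Osteoblasts led in the collagenase Mmp13 (3221 CPM, SD 1572, n = 3 libraries; log2 fold 11.84, SE 0.19) and Col6a3 (1001 CPM, SD 459.6). They held 13 of the 29 collagens that were called and highest in 1 class at 50 CPM or more. Neutrophils led in the granule proteases Mmp8 (3015 CPM, SD 99.3; 8.92, SE 0.17) and Mmp9 (2056 CPM, SD 169.7; 8.13, SE 0.13). By that count, of 10 class II genes of the major histocompatibility complex (MHC), 5 were highest in conventional dendritic cells, 3 in B cells and 2 in macrophages. Of 38 interferon-stimulated genes highest and called in 1 class, macrophages held 9, blood endothelial cells 8 and monocytes 6. Among the last was Ifitm3, an antiviral membrane protein gene (3243 CPM, SD 651). Among the 20 classes B cell progenitors led in 34 of 36 cell cycle genes, such as Ube2c (754 CPM, SD 206). Unnamed cluster 30, with the cell cycle genes Tk1, Birc5 and Kif23 among its 10 leading genes, was not compared. Neither was unnamed cluster 5, which matched fibroblasts best by markers. Type 2 innate lymphoid cells led in 64 of 83 cytosolic ribosomal protein genes, and choroid plexus or ependymal cells in 44 of 75 nuclear genes of oxidative phosphorylation. Over 981 list genes tested in 20 classes, edgeR with a library block made 5641 calls of a higher level in a class, or 5715 adjusted over the list alone. In all 970 genes were highest in 1 class and called there, at any level. The named genes had adjusted p from 1.20e-57 to 6.05e-09. The 5641 calls fell to 3232 when cells above 5% mitochondrial UMIs were left out, where 13 of the 20 classes still had enough cells to be fitted.

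In T cells of the older libraries Gzmk, a granule protease gene, was higher, at 128 CPM against 22.4 CPM at 2 months (log2 fold 2.47, SE 0.42, adjusted p 0.0182, n = 2 against 2 libraries). The granzyme B gene Gzmb was at 53.7 against 14.7 CPM (1.86, SE 0.33, adjusted p 0.0203). Eomes, a transcription factor of cytotoxic lymphocytes, was at 99.4 against 29.1 CPM (1.78, SE 0.26, adjusted p 0.00911). The drug efflux pump gene Abcb1a (1.71, SE 0.18, adjusted p 0.00190) and Ttn (3.17, SE 0.49, adjusted p 0.0106) were higher too. So were Ifngas1, a noncoding RNA beside Ifng (2.15, SE 0.43, adjusted p 0.0339), Gpm6b (1.96, SE 0.32), Ahi1 (1.68, SE 0.28) and Lilr4b (1.64, SE 0.30). Cd163l1, a scavenger receptor gene, was lower, at 49.9 against 368 CPM (−2.92, SE 0.24, adjusted p 0.000452). Sox13, a transcription factor of gamma delta T cells that make interleukin 17, was at −2.60 (SE 0.31, adjusted p 0.00344), and Auts2 was at −2.59 (SE 0.35, adjusted p 0.00716). Cluster 18, led by Cd163l1, Trdc and Il17re, held 6.83% and 7.14% of T cells in the older libraries and 29.3% and 35.6% at 2 months. Igkc, an immunoglobulin gene of plasma cells, was higher (5.45, SE 0.82, adjusted p 0.0101). Col1a1, Col1a2, Sparc, Mgp, Igfbp5, Gpx3 and the mast cell protease gene Mcpt4 were lower, with folds from −3.35 for Col1a1 to −2.51 for Mgp. Each of these 7 was at a level that free RNA could supply.

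In T cells 225 of 10172 genes tested were called, 67 higher and 158 lower with age, with 1427 at an unadjusted p under 0.05. Of the 225, 28 lay at a level that free RNA could supply. The count was 435, 804, 15 and 0 without replicates 1, 2, 3 and 4 in turn. In edgeR without replicate 4, 792 were at an unadjusted p under 0.05, and DESeq2 over all libraries called 158. The count was 54 with cells above 5% mitochondrial UMIs left out, 119 with equal cell numbers per library, 647 with no filter on low counts and 16 in cluster 2 alone, a setting chosen after seeing the data. Of the 20 genes named by rule, 5 were called without replicate 3 (Col1a2, Igfbp5, Cd163l1, Sparc and Mgp) and 0 without replicate 4 in edgeR. All 20 kept their sign, Gzmk at 2.06 and 3.22 in those fits and Cd163l1 at −2.94 and −2.89. Without replicate 1 Ttn was at 2.11, Gzmk at 1.63 and Gzmb at 1.24, and Igkc was at 3.45 without replicate 2. In cluster 2 alone Gzmk was at 1.95, Gzmb at 1.29, Eomes at 1.28, Ttn at 2.91 and Auts2 at −0.62, none of them called there. Neither were Cd163l1 (−0.57, adjusted p 0.928) and Sox13 (−0.33, adjusted p 0.973), the genes of cluster 18. Still called in cluster 2 were Igkc (5.64), Abcb1a (1.31), Col1a1 (−3.98), Col1a2 (−3.28), Igfbp5 (−2.93), Gpx3 (−2.83), Sparc (−3.02) and Mgp (−2.51). The other 5 named genes kept their sign and were not called there: Ifngas1 at 1.67, Gpm6b at 1.74, Ahi1 at 1.71, Lilr4b at 1.20 and Mcpt4 at −3.31. Gzmk was also not called by DESeq2 or with equal cell numbers, Ahi1 and Lilr4b with equal cell numbers, nor Ttn, Ifngas1, Gpm6b, Lilr4b and Sox13 at 5% mitochondrial UMIs, and each kept its sign.

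Macrophages of the older libraries had more transcript of the B cell attractant Cxcl13, at 37.9 against 0.770 CPM (log2 fold 5.53, SE 0.46, adjusted p 0.00135, n = 2 against 2 libraries). Cd5l, a scavenger receptor family gene of tissue macrophages, was at 35.0 against 0.393 CPM (6.37, SE 1.04, adjusted p 0.0351). Interferon-inducible genes were higher, with Ifi44 at 1.64 (SE 0.18, adjusted p 0.00647), the GTPase gene Iigp1 at 1.54 (SE 0.19, adjusted p 0.0111) and Tgtp2 at 1.75 (SE 0.29, adjusted p 0.0394). Ly6a was at 149 against 41.4 CPM (1.85, SE 0.20, adjusted p 0.00647). Tnfaip2 (1.56, SE 0.24) and Csprs (2.11, SE 0.28) were higher as well. Retnla, a gene of alternatively activated macrophages, was lower, at 9.90 against 263 CPM (−4.71, SE 0.65, adjusted p 0.0128). So were the lysozyme gene Lyz1 (−2.09, SE 0.35, adjusted p 0.0394), the adaptor gene Dok2 (−1.44, SE 0.18), Lmna of the nuclear lamina (−1.39, SE 0.21) and the imprinted RNA H19 (−1.56, SE 0.22). Retnlg and Jchain, markers of neutrophils and plasma cells, were higher (2.41 and 2.09). Col1a1, Col1a2, Mfap4, Igfbp5 and Igfbp7 were lower (−2.16, −1.71, −2.23, −1.73 and −1.47). All 7 lay at a level that free RNA could supply. H19 lay above such a level in macrophages but was called lower in 4 classes. In free RNA it was at 49.5 CPM in the older libraries and 302 CPM at 2 months (−2.58).

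In macrophages 36 of 10753 genes were called, 24 higher and 12 lower, with 1129 at an unadjusted p under 0.05. The count was 90, 90, 62 and 53 without replicates 1 to 4. It was 21 with lower count minimums, 14 with 5% and 17 with 20% as the mitochondrial limit (the latter chosen after seeing the data), and 20 with list genes kept in clustering. It was 379 with no filter on low counts, 17 without genes that free RNA could supply and 16 with equal cell numbers. Of the 20 genes named by rule 16 passed in each leave-one-out fit. Tgtp2 was lost without replicates 1 (1.62) and 4 (1.43), Mfap4 without 1 (−2.09) and 4 (−1.81), Lyz1 without 1 (−1.65), and Igfbp7 without 2 (−1.24) and 3 (−1.39). Cd5l was at 62.8 CPM in replicate 1 and 7.26 CPM in replicate 2, with a fold of 4.10 without replicate 1. Retnla lost the call in 7 other settings, Lyz1 in 10, Tgtp2 in 8, Tnfaip2 and Lmna in 4, Cd5l in 3 and Ly6a with equal cell numbers, each with its sign kept.

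Neutrophils of the older libraries had more transcript of BC100530, a stefin family gene of cysteine protease inhibitors, at 51.8 against 4.72 CPM (log2 fold 3.13, SE 0.39, adjusted p 0.00568, n = 2 against 2 libraries). Stfa2, a further stefin gene, was at 21.4 against 3.00 CPM (2.83, SE 0.40, adjusted p 0.00986). Igkc and Jchain were higher (2.53 and 2.88). Genes of fibroblasts and matrix were lower, among them Dcn (−3.61, SE 0.44), Bgn (−3.48, SE 0.53), Ogn (−2.90, SE 0.46), Col1a1 (−2.55, SE 0.34) and Col1a2 (−2.85, SE 0.51). Tpsb2, a tryptase gene of mast cells, was lower too (−3.09, SE 0.46). Each of these lay at a level that free RNA could supply. Of 8749 genes tested 22 were called, 4 higher and 18 lower (366 at an unadjusted p under 0.05), and 20 of them lay at such a level. The count was 131, 80, 12 and 0 without replicates 1 to 4. In edgeR without replicate 4, 197 were at an unadjusted p under 0.05, and DESeq2 called 28 over all libraries. The count was 42 with a mitochondrial limit of 20%, 50 with doublets kept, 41 with list genes kept in clustering, 121 with no filter on low counts and 2, Stfa2 and BC100530, without genes that free RNA could supply. Of the 14 genes named by rule 8 were called without replicate 3 and 0 without replicate 4 in edgeR, with folds of 3.41 and 2.68 for Stfa2 and of 5.65 and 2.74 for BC100530. BC100530 was not called by DESeq2 or with equal cell numbers, nor Stfa2 in the largest cluster alone.

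**Figure D2:**
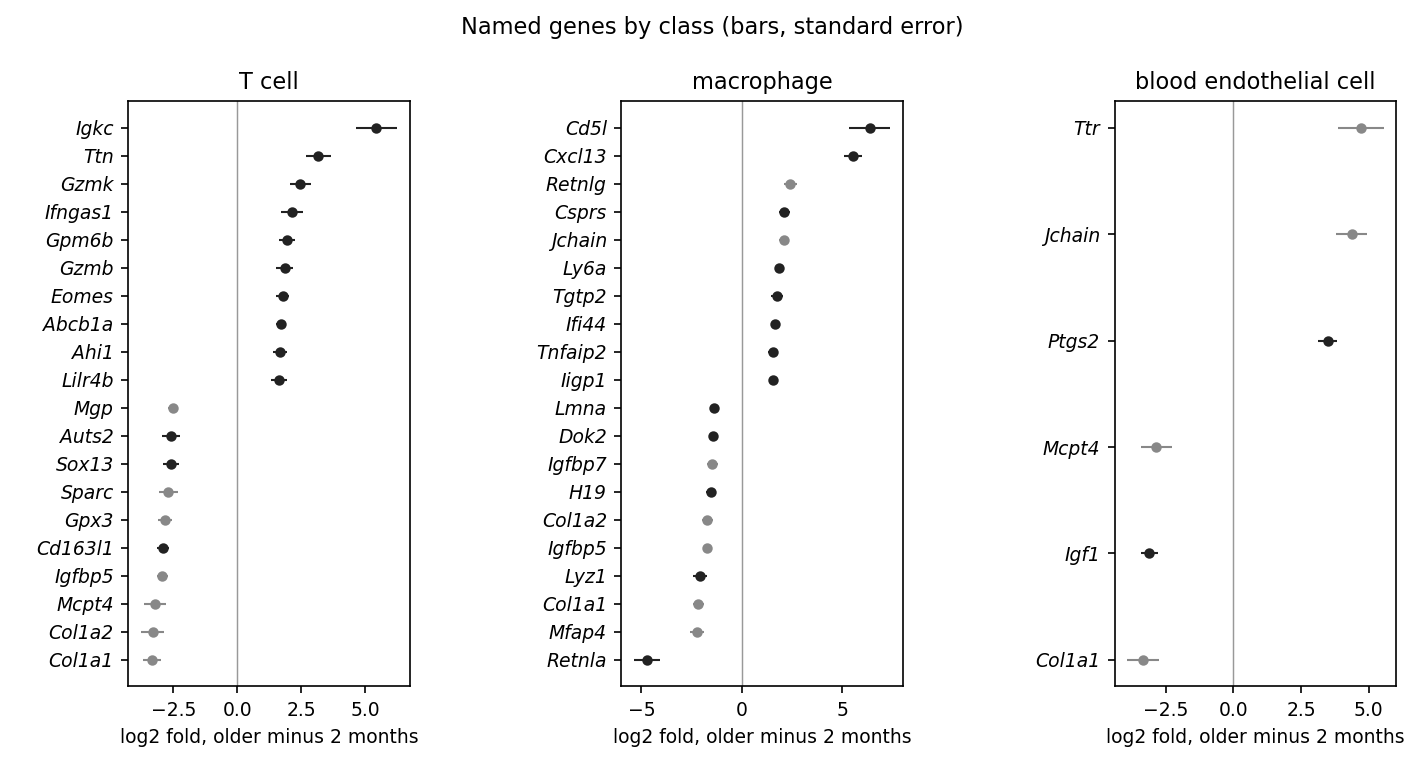
Log2 fold of the named genes between 9 or 14 months and 2 months in T cells, macrophages and blood endothelial cells, with bars of 1 standard error. Positive values are higher in the older libraries, and grey points are genes at a level that free RNA could supply, such as Igfbp5 in macrophages (−1.73), against Cxcl13 (5.53) and Retnla (−4.71), which are not.

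Blood endothelial cells of the older libraries had more transcript of Ptgs2, the inducible cyclooxygenase gene, at 183 against 17.0 CPM (log2 fold 3.49, SE 0.35, adjusted p 0.00149, n = 2 against 2 libraries). The growth factor gene Igf1 was lower, at 7.27 against 62.4 CPM (−3.10, SE 0.32, adjusted p 0.00149). Both passed in each leave-one-out fit. Ptgs2 was at 1.40 and not called in the largest endothelial cluster alone, a setting chosen after seeing the data. Cluster 27, led by the barrier genes Cldn5, Slc2a1 and Slco1a4, held 29.1% and 23.8% of the class in the older libraries and 5.66% and 12.1% at 2 months. Ttr of the choroid plexus (4.71), Jchain (4.37), Col1a1 (−3.32) and Mcpt4 (−2.85) also changed, at levels that free RNA could supply. They were lost without replicate 1 (2.73, 4.65, −1.96 and −1.90) or, for Mcpt4, replicate 4 (−2.40), and Col1a1 was at −5.47 without replicate 2. In free RNA Ttr moved the other way, at 10416 CPM in the older libraries and 18307 CPM at 2 months (−0.81). Ptgs2 and Igf1 lay above a level that free RNA could supply, but moved in free RNA in the same directions as in these cells (1.31 and −2.34). In all 117 of 9835 genes were called, 83 higher and 34 lower (1106 at an unadjusted p under 0.05), with 52 without replicate 1 and 232 without replicate 4. The count was 179 with lower count minimums, 193 with 20% as the mitochondrial limit, 510 with no filter on low counts and 18 in the largest cluster alone (855 at an unadjusted p under 0.05).

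Fibroblasts of the older libraries had more transcript of Tcf21, a transcription factor of mesenchymal progenitors, at 51.5 against 0.705 CPM (log2 fold 6.00, SE 0.33, adjusted p 0.000500, n = 2 against 2 libraries). Higher too were the retinol oxidising enzyme gene Adh1 (5.01, SE 0.67, adjusted p 0.0434) and the laminin gene Lamc3 (4.03, SE 0.43, adjusted p 0.0181). The last 2 were lost without replicate 1 (2.65 and 3.74), and Adh1 in 4 and Lamc3 in 2 other settings. Cluster 9, led by Nov, Penk and F3, held 56.2%, 16.1%, 45.8% and 68.2% of fibroblasts in replicates 1 to 4, and cluster 14, led by Lum and Pappa2, the rest. Of 11406 genes 15 were called, all higher (1141 at an unadjusted p under 0.05). In turn 74, 55, 152 and 77 were called without replicates 1 to 4 and 63 by DESeq2, of which 20, 7, 33, 19 and 13 were lower. The count was 24 (1 lower) with lower count minimums, 13 (4 lower) with higher ones, 28 (4 lower) with doublets kept, 31 (6 lower) with list genes kept in clustering, 373 (120 lower) with no filter on low counts and 119 (20 lower) in the largest cluster alone. It was 6 with 20% as the mitochondrial limit, 3 with equal cell numbers and 10 with unnamed clusters of fibroblast markers counted in.

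Conventional dendritic cells of the older libraries had more transcript of Ly6a (log2 fold 2.08, SE 0.25, adjusted p 0.0221, n = 2 against 2 libraries) and Csprs (1.72, SE 0.20, adjusted p 0.0221). Plxdc2 was lower (−2.75, SE 0.30, adjusted p 0.0209). Natural killer cells had less of Birc5, a gene of dividing cells, at 3.51 against 44.5 CPM (−3.59, SE 0.50, adjusted p 0.0273). Type 2 innate lymphoid cells had more of the sialyltransferase gene St8sia6 (3.23, SE 0.48, adjusted p 0.0181). Of these, Ly6a passed in each leave-one-out fit. Csprs was lost without replicates 2 (1.57), 3 (1.69) and 4 (1.78), Plxdc2 without 2 (−2.35), Birc5 without 1 (−4.31) and 2 (−3.23), and St8sia6 without 1 (2.60) and 4 (2.67). Ly6a was not called with 5% as the mitochondrial limit or with equal cell numbers, nor Birc5 with that limit, by DESeq2 or without genes that free RNA could supply.

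With edgeR and all 4 libraries the fewest genes were called in monocytes and B cells. In B cells Gpx3 (log2 fold −3.74, SE 0.45), Igfbp5 (−2.83, SE 0.29) and Mgp (−2.73, SE 0.29) were lower in the older libraries, and in monocytes Igkc was higher (2.93, SE 0.29, adjusted p 0.0312), all at levels that free RNA could supply. Most B cells came from cluster 12 in replicates 1 and 2 (80.8% and 74.0%), led by Ighd and Fcer2a, and from cluster 19 in replicates 3 and 4 (57.8% and 70.9%), led by Ms4a1 and Tnfrsf13c. Genes called with age by edgeR were 3 of 7998 in B cells (653 at an unadjusted p under 0.05, 13 by DESeq2) and 1 of 9229 in monocytes (417, and 9 by DESeq2). They were 5 of 7369 in natural killer cells (698, and 8 by DESeq2), 21 of 10519 in conventional dendritic cells (1230, and 57 by DESeq2) and 23 of 9209 in type 2 innate lymphoid cells (713, and 19 by DESeq2). Without replicates 1 to 4 the edgeR counts were 286, 609, 0 and 0 in B cells (365 and 321 at an unadjusted p under 0.05 in the last pair) and 16, 6, 18 and 0 in monocytes (947 in the last). They were 5, 4, 47 and 45 in natural killer cells, 40, 3, 26 and 15 in conventional dendritic cells, and 30, 11, 79 and 6 in type 2 innate lymphoid cells. The 3 B cell genes and Igkc in monocytes were not called without replicate 3 (Gpx3 −4.01, Igkc 2.70) or 4 (Gpx3 −3.39, Igkc 3.16). The B cell count was 6 with 20% as the mitochondrial limit, 267 with no filter on low counts, 8 with equal cell numbers, 1 in the largest cluster and, in edgeR without genes that free RNA could supply, 0 (620 at an unadjusted p under 0.05). In monocytes it was 2 with doublets kept, 142 with no filter and 11 in the largest cluster. It was 0 there in edgeR with lower or higher count minimums, mitochondrial limits of 5% or 20%, list genes kept in clustering or no genes that free RNA could supply (413, 536, 487, 342, 424 and 383 at an unadjusted p under 0.05). In natural killer cells it was 3 and 8 with lower and higher minimums, 2 and 12 with limits of 5% and 20%, 10 with doublets kept, 47 higher and 76 lower with no filter, 11 with equal cell numbers and 0 in edgeR without genes that free RNA could supply (684). In conventional dendritic cells it was 12 with lower minimums, 8 at 5%, 44 at a resolution 2 times as high, 9 with list genes kept, 383 with no filter, 7 without genes that free RNA could supply and 36 in the largest cluster. In type 2 innate lymphoid cells it was 47 with doublets kept, 37 with list genes kept, 188 with no filter, 13 without genes that free RNA could supply and 35 with equal cell numbers. Over the 10 classes 468 of 95239 tests were called, 223 higher and 245 lower, with 8880 at an unadjusted p under 0.05. Of the 468, 90 were at a level that free RNA could supply.

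Interferon-stimulated genes, which cells turn on in answer to interferons, moved in opposite directions in different classes. As a list they rose in the older libraries in conventional dendritic cells (median log2 fold 0.61, 39 of 41 genes positive, adjusted p 3.55e-16, camera), fibroblasts (0.75, 33 of 36, adjusted p 4.29e-11) and macrophages (0.42, 38 of 41, adjusted p 8.45e-11). They rose too in T cells (0.36, 35 of 40, adjusted p 2.64e-05) and type 2 innate lymphoid cells (0.29, 21 of 27, adjusted p 0.00994). They fell in monocytes (−0.77, 0 of 41 positive, adjusted p 3.06e-18), neutrophils (−0.76, 0 of 32, adjusted p 3.13e-14) and B cells (−0.61, 3 of 27, adjusted p 4.48e-11). The list did not pass in blood endothelial or natural killer cells. Each of these calls has an adjusted p of 0.740 to 0.828 with an estimated correlation between genes, where so few libraries leave camera little power.

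**Figure D3:**
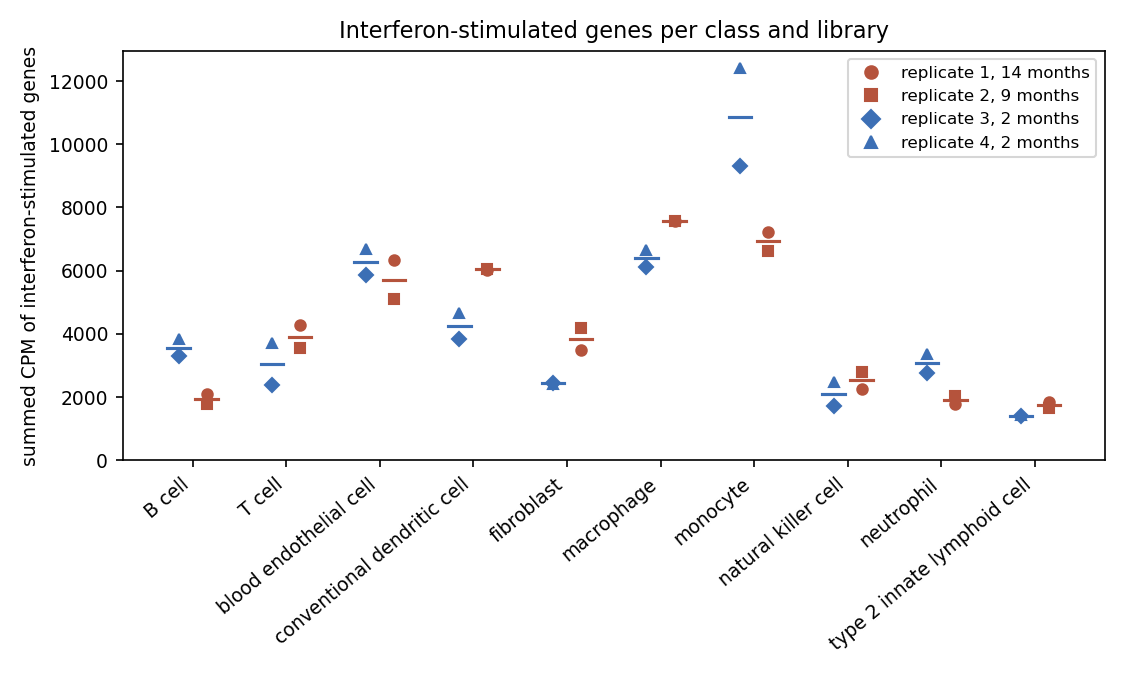
Summed level of the interferon-stimulated genes, in CPM, in each class and library. Each point is 1 library, red for 9 or 14 months and blue for 2 months, and each line is the mean of a group. Monocytes were at 7214 and 6638 in the older libraries and 9313 and 12410 at 2 months, conventional dendritic cells at 6028 and 6052 against 3850 and 4670.

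Conventional dendritic cells had 3 members called over all genes and 24 adjusted over the list alone. Among the 3 were Irf7, the regulator of type I interferon genes (log2 fold 1.53, SE 0.13, adjusted p 0.0162), and the ubiquitin-like modifier Isg15 (1.28, SE 0.19, adjusted p 0.0428), each higher in both older libraries. Macrophages had 3 and 12 (Ifi44, Iigp1 and Irf7 at 1.05, SE 0.17, adjusted p 0.0323). Fibroblasts had 0 over all genes with edgeR (22 at an unadjusted p under 0.05, 3 by DESeq2) and 18 adjusted over the list alone (such as Ifit3 at 1.10, SE 0.23). In monocytes and neutrophils 0 members passed over all genes with edgeR (22 and 18 at an unadjusted p under 0.05, 2 and 1 by DESeq2). Adjusted over the list alone 22 and 14 were lower, such as Isg15 in monocytes (−1.50, SE 0.30, adjusted p 0.00982 over the list) and Rsad2 in neutrophils (−1.13, SE 0.25, adjusted p 0.0113 over the list). B cells had 0 over all genes (12 at an unadjusted p under 0.05, 1 by DESeq2) and 10 lower adjusted over the list alone (Rtp4 at −3.21, SE 0.54). T cells and type 2 innate lymphoid cells had 0 over all genes with edgeR and DESeq2 (10 and 7 higher and 1 and 2 lower at an unadjusted p under 0.05). Adjusted over the list alone there were 0 in T cells and, in the lymphoid cells, 1 higher and 1 lower (Iigp1 at 1.65 and Cxcl10 at −3.10). The list kept its call in each leave-one-out fit in 6 of the 8 classes. It was lost in T cells without replicate 3 (0.12) and in type 2 innate lymphoid cells without replicates 1 (0.093) and 3 (0.23), and in the largest T cell cluster alone (0.16). Its median moved by over 1.5 times in macrophages without replicate 2 (0.26), in T cells without replicate 4 (0.69), in B cells without replicate 1 (−1.01) and in monocytes without replicate 4 (−0.39). In free RNA the list had a median log2 fold of −0.11, with 16 of 41 genes positive.

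**Figure D4:**
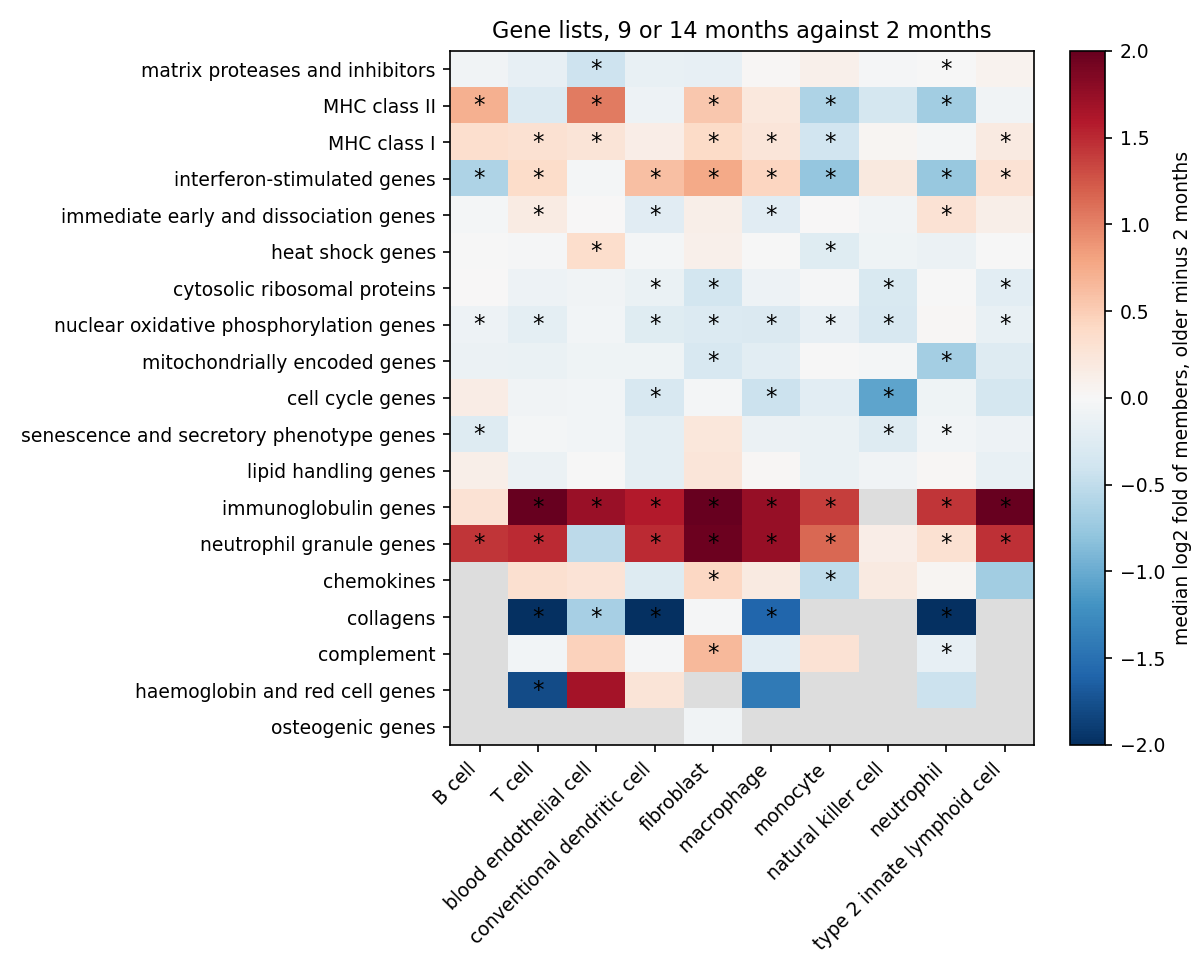
Median log2 fold of each gene list between 9 or 14 months and 2 months, by cell class, on a colour scale from −2 to 2. Stars mark lists with a camera adjusted p under 0.05, and grey cells had under 5 genes tested. Interferon-stimulated genes ran from −0.77 in monocytes to 0.75 in fibroblasts.

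Genes of energy metabolism, translation and division were lower in the older libraries in several classes. Nuclear genes of oxidative phosphorylation, which encode subunits of the respiratory chain, fell as a list in 8 of 10 classes, by small amounts. Macrophages had a median of −0.29 (3 of 74 positive, adjusted p 1.12e-11) and natural killer cells of −0.32 (5 of 71, adjusted p 5.64e-09). Conventional dendritic cells were at −0.25 (3 of 73, adjusted p 5.94e-11) and fibroblasts at −0.27 (4 of 73, adjusted p 4.94e-09). In these 4 classes 0 members passed over all genes with edgeR or DESeq2, or adjusted over the list alone (20, 17, 30 and 10 lower at an unadjusted p under 0.05). Cytosolic ribosomal protein genes fell in fibroblasts (−0.37, 3 of 81, adjusted p 3.75e-12), natural killer cells (−0.30, 5 of 81, adjusted p 2.55e-08), conventional dendritic cells (−0.14) and type 2 innate lymphoid cells (−0.20). Cell cycle genes fell in natural killer cells (−1.05, 1 of 25 positive, adjusted p 1.06e-11). Of them 1 was called over all genes (Birc5) and 12 adjusted over the list alone, such as Stmn1 (−2.04, SE 0.38) and Tpx2 (−2.63, SE 0.56). Ccnb2 had no count in the natural killer cells of either older library and was at least 5.53-fold lower there than at 2 months (floor of 3 counts per library). The median was −1.05 with Ccnb2 at that bound too. They also fell in conventional dendritic cells (−0.32, adjusted p 2.58e-07) and macrophages (−0.43, adjusted p 0.000464). With an estimated correlation the lists of this paragraph had an adjusted p of 0.740 to 0.860. In free RNA the medians were −0.52 for oxidative phosphorylation, −0.25 for ribosomal protein genes and 0.30 for cell cycle genes. The transcript Gm42418 took 86492, 311677, 57429 and 84348 CPM of the free RNA of replicates 1 to 4.

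The fall of oxidative phosphorylation genes passed in each leave-one-out fit in 6 of the 8 classes. It was lost in monocytes without replicates 1 (−0.11) and 3 (−0.054) and in B cells without replicates 2 (0.039) and 4 (−0.14). Without replicate 1 the median was −0.27 in B cells and −0.48 in fibroblasts. Ribosomal protein genes lost the call in conventional dendritic cells without replicate 1 (−0.12) and in type 2 innate lymphoid cells without replicate 3 (−0.14), and cell cycle genes in conventional dendritic cells without replicate 1 (−0.19). Without replicate 2 these medians were −0.13 for ribosomal protein genes in type 2 innate lymphoid cells and −0.50 for cell cycle genes in conventional dendritic cells. In natural killer cells the cell cycle median was −2.40 without replicate 1. In macrophages the call was lost with lower count minimums (−0.21), with 5% as the mitochondrial limit (−0.14) and with list genes kept in clustering (−0.18).

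Antigen presentation genes were higher in some classes of the older libraries and lower in others. MHC class II genes, which present peptides to helper T cells, rose in B cells (median log2 fold 0.71, 10 of 10 positive, adjusted p 1.14e-05). Of them 0 passed over all genes in edgeR and DESeq2 (7 at an unadjusted p under 0.05) and 7 adjusted over the list alone, such as the class II transactivator Ciita (0.98, SE 0.28) and H2-Aa (0.76, SE 0.20). They rose too in blood endothelial cells (1.04, adjusted p 0.0382) and fibroblasts (0.55, adjusted p 0.0404). They fell in neutrophils (−0.70, adjusted p 0.00639) and monocytes (−0.62, adjusted p 0.0414). MHC class I genes rose in fibroblasts (0.39, 12 of 14, adjusted p 0.000308), macrophages (0.24, 13 of 14, adjusted p 0.000445), T cells (0.31), blood endothelial cells (0.25) and type 2 innate lymphoid cells (0.17). They fell in monocytes (−0.38, 0 of 14, adjusted p 0.000201). With an estimated correlation these lists had an adjusted p of 0.740 to 0.860. Their medians in free RNA were −0.17 for class II and 0.097 for class I. In B cells, where cluster 12 held most older cells and cluster 19 most 2-month cells, the class II median was 0.15 and not called in cluster 12 alone, with H2-Aa at −0.014.

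Of the 11 calls in that pair of lists, class II in B cells and class I in fibroblasts passed in each leave-one-out fit. Class II was lost in blood endothelial cells without replicates 1 (0.033) and 3 (0.65), in fibroblasts without 1 (0.35) and 3 (0.23) and in 5 other settings. It was lost in neutrophils without 2 (−0.49), 3 (−0.65) and 4 (−0.43) and in monocytes without 1 (−0.58), with the opposite sign there without 4 (0.48). Class I was lost in blood endothelial cells without 1 (−0.019), 3 (0.24) and 4 (0.32), in macrophages without 1 (0.12) and in T cells without 1 (0.18). It was lost in type 2 innate lymphoid cells without 1 (0.12), 3 (0.19) and 4 (0.17), and in monocytes without 2 (−0.27) and 4 (−0.22). Class II was at 0.95 in fibroblasts without 4 and −1.22 in monocytes without 3. Class I without 2 was at 0.57 in blood endothelial cells, 0.51 in T cells, 0.39 in macrophages and 0.31 in type 2 innate lymphoid cells.

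Chemokine and complement genes rose in fibroblasts of the older libraries. The monocyte attractant Ccl7 was called over all genes (log2 fold 3.93, SE 0.29, adjusted p 0.00182). In all 6 chemokines were higher and 1 lower adjusted over the list alone, among them Ccl2 (1.86, SE 0.36), the eosinophil attractant Ccl11 (2.55, SE 0.52) and, lower, Cxcl14 (−2.17, SE 0.46). The list had a median of 0.42 (11 of 16 positive, adjusted p 0.0311, and 0.740 with an estimated correlation). The complement genes C4b (1.06, SE 0.22) and C2 (1.03, SE 0.27) were among 5 that passed adjusted over the list alone. Over all genes 0 did in edgeR (6 at an unadjusted p under 0.05, 1 by DESeq2), and the list had a median of 0.66 (11 of 13, adjusted p 0.00194, and 0.740 with an estimated correlation). In monocytes the chemokine list fell (−0.50, adjusted p 0.0146, and 0.740 with an estimated correlation), with medians of −1.25, −0.83 and −0.13 without replicates 1, 2 and 3. Of its 11 members 0 passed over all genes by edgeR or DESeq2 (1 higher and 5 lower at an unadjusted p under 0.05). Cxcl9 and Cxcl10, ligands of Cxcr3, were at −4.69 (SE 0.90) and −3.54 (SE 0.81), with adjusted p of 0.418 and 0.423 over all genes and 0.00639 and 0.0103 over the list alone. Complement genes fell in neutrophils (−0.17, adjusted p 0.00655, and 0.740 with an estimated correlation). The fibroblast chemokine list was not called without replicate 2 (0.28) or in 5 other settings, of which higher count minimums and equal cell numbers gave the opposite sign, and had a median of 1.48 without replicate 3. The fibroblast complement list was not called with higher count minimums or with doublets kept, with medians of 1.05 and 1.16 without replicates 1 and 3. The neutrophil complement list was not called without replicate 3 (−0.19) and was at −0.41 and −0.28 without 1 and 2. In endothelial cells heat shock genes rose (0.35, adjusted p 0.0130, and 0.799 with an estimated correlation), with the chaperone gene Hspa1a called (1.35, SE 0.25, adjusted p 0.0393), and were not called without replicate 2 (0.017) and at 0.63 without replicate 1. Chemokine, complement and heat shock genes had free RNA medians of −0.53, −0.65 and −0.27.

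Collagen, immunoglobulin and neutrophil granule genes moved in several classes at once. Collagens fell in T cells (median log2 fold −3.33, 0 of 6 positive, adjusted p 1.36e-10), neutrophils (−2.70, 2 of 10, adjusted p 3.75e-12) and conventional dendritic cells (−2.20, 1 of 10, adjusted p 4.62e-07). They fell in macrophages (−1.58, 3 of 13, adjusted p 1.18e-07) and blood endothelial cells (−0.67, 4 of 17, adjusted p 4.75e-05). In T cells 5 collagens were called and 6 adjusted over the list alone, and in neutrophils 4 and 7. In macrophages 3 and 8 were lower, with Col27a1 higher (1.35, SE 0.23), and conventional dendritic cells had 0 with edgeR (7 at an unadjusted p under 0.05, 2 by DESeq2) and 7. Blood endothelial cells had 4 lower over all genes and 7 adjusted over the list alone. Among them were the basement membrane genes Col15a1 (−1.33, SE 0.21, adjusted p 0.0185), Col4a1 (−1.05, SE 0.17, adjusted p 0.0234) and Col4a2 (−0.94, SE 0.17, adjusted p 0.0387), which free RNA could not supply. These 5 lists passed in each leave-one-out fit. Without replicate 4 the median was −1.33 in conventional dendritic cells and −1.08 in blood endothelial cells. Each list had an adjusted p of 0.740 with an estimated correlation. Col15a1 and Col4a1 were not called in the largest endothelial cluster alone (−0.98 and −0.80). The collagen list had a median of −0.65 in free RNA. Col1a1, Col1a2 and Col3a1, called lower in 5, 3 and 3 classes, fell by more there (−2.15, −2.18 and −2.47). Each of those calls lay at a level that free RNA could supply.

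Immunoglobulin genes rose in 8 of the 9 classes where they were tested, with a median log2 fold from 1.39 in monocytes to 2.60 in fibroblasts. Neutrophil granule genes rose in 8 of 10, with a median of 0.31 in neutrophils themselves (12 of 12 positive, adjusted p 0.0201), 1.43 in B cells and 1.96 in fibroblasts. In neutrophils that call was lost without replicates 1 (0.14) and 4 (0.017). In free RNA the immunoglobulin list had a median of 1.89 and the granule list of 1.50. Each call had an adjusted p of 0.740 to 0.846 with an estimated correlation. Genes called in 3 or more classes numbered 18, 6 higher and 12 lower, with 69 calls in all. Igfbp5 and Mgp, genes of fibroblasts and mural cells, were each lower in 6 classes, Col1a1 in 5, and Igkc and Jchain were higher in 5. In free RNA Igfbp5 was at 544 CPM in the older libraries and 2536 at 2 months, Mgp at 878 and 3251, Igkc at 7589 and 1372, and Jchain at 665 and 133. Of the granule lists 6 of 8 passed in each leave-one-out fit, the other loss being in monocytes without replicate 4 (0.42). Of the immunoglobulin lists 5 of 8 did, with losses without replicate 1 in fibroblasts (1.77) and macrophages (1.05) and without replicate 4 in conventional dendritic cells (2.10). Without replicate 3 the immunoglobulin median was 5.68 in T cells, 4.19 in blood endothelial cells, 6.998 in conventional dendritic cells, 4.08 in fibroblasts, 2.98 in monocytes and 3.38 in type 2 innate lymphoid cells. It was 2.47 and 2.88 in monocytes and 2.14 and 3.02 in neutrophils without replicates 2 and 4, and 2.99 in conventional dendritic cells without 1. Without replicates 3 and 4 the granule median was 2.41 and 0.73 in B cells, 2.52 and 0.72 in T cells, 3.32 and 0.92 in macrophages and 2.89 and 0.76 in type 2 innate lymphoid cells. It was 0.90 in T cells without 1, 1.25 in fibroblasts without 4, 3.61 in monocytes without 3, and 0.51 and 0.64 in neutrophils without 2 and 3.

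The fold between the older and the 2-month libraries differed between classes when the difference itself was tested. Free RNA and the mix of clusters within a class were not set apart from age in these tests. Between T cells and macrophages 110 of 11442 genes differed, 24 with a higher fold in T cells and 86 with a lower one (1035 at an unadjusted p under 0.05). Between T cells and neutrophils 30 of 11282 did, 13 higher and 17 lower (766), and between macrophages and neutrophils 20 of 11563, 18 higher and 2 lower (677). Interferon-stimulated genes were among them: Oasl2, an oligoadenylate synthase homologue, had a fold higher by 1.51 in macrophages and by 2.37 in T cells than in neutrophils. Rsad2, the gene of the antiviral enzyme viperin, had a fold higher by 1.97 and 2.12 and Irf7 by 1.44 in macrophages. Without replicates 1 to 4 the counts were 84, 173, 69 and 109 for T cells and macrophages and 76, 152, 3 and 47 for T cells and neutrophils. They were 75, 94, 14 and 0 for macrophages and neutrophils (edgeR, 366 at an unadjusted p under 0.05 in the last). The first pair was at 176 with lower count minimums, 66 with 5% as the mitochondrial limit and 35 in the largest clusters, the second at 115 and the third at 107 with higher count minimums.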

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

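The tests of free RNA below and the separate tests of the T cell genes called higher and lower were chosen only after the result was seen.

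In 6 of 84 groups of 4 libraries (21 shares and 63 gene levels), 1 library lay apart from the rest by more than a 95% limit allows (gap over range, Dixon's test), which chance does in about 1 in 20 groups. B cells held 10.9% of replicate 2, against 2.93% to 4.23% in the others. Col13a1 in blood endothelial cells was at 206.7 CPM in replicate 2 (others 130.0 to 131.8) and Slc26a7 in fibroblasts at 312.5 CPM in replicate 2 (others 417 to 423). In replicate 3, Ccl22 in conventional dendritic cells was at 202.7 CPM (others 47.5 to 73.0), Ccl12 in macrophages at 306 CPM (others 231 to 243) and Il2ra in type 2 innate lymphoid cells at 465.5 CPM (others 352 to 369).

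The fold with age of several named genes differed between 2 classes when the difference was tested in edgeR, in log2 units. Between macrophages and neutrophils it was higher in macrophages for Irf7 by 1.44, Oasl2 by 1.51, Mgp by 1.95, Rsad2 by 1.97, Usp18 by 2.00, Gpx3 by 2.11, Dcn by 2.24 and Mmp8 by 2.78 (adjusted p 0.00639 to 0.0179); Mgp and Dcn in both classes, Gpx3 in neutrophils and Mmp8 in macrophages lay at a level that free RNA could supply, where they moved by −1.89, −1.94, −2.55 and 1.65. Between T cells and macrophages the difference was −1.96 for Sparc, −1.85 for Gpx3, −1.68 for Tgtp2, −1.58 for Mgp, −1.55 for Ly6a, −1.16 for Igfbp5, 1.04 for Dok2, 1.35 for Lilr4b and 2.19 for Ier3 (adjusted p 0.000706 to 0.0342). Sparc (−2.02 in free RNA), Mgp and Igfbp5 (−2.22) in both classes and Gpx3 in T cells lay at such a level. Between T cells and neutrophils it was −1.88 for Hbb-bs, 1.69 for Ifi27l2a, 2.05 for Ahi1, 2.12 for Rsad2 and 2.37 for Oasl2 (adjusted p 0.00187 to 0.0281), with Hbb-bs at such a level in neutrophils (0.23 in free RNA).

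Of the cells, 11.2% lay in 8 clusters outside the named classes, which the comparisons do not use, and their shares were not tested for age. Cluster 5, led by the cartilage genes Chad, Comp and Matn4, held 5.87% of all cells, with 1.15%, 0.529%, 8.73% and 11.9% in replicates 1 to 4. Cluster 16, led by Rag1 and Vpreb3, held 2.36% (1.50%, 5.09%, 2.19% and 0.733%), with replicate 2 above the rest. Cluster 30, led by Acp5 and with the cell cycle genes Tk1, Birc5 and Kif23 among its leading genes, held 0.950% (0.396%, 0.346%, 1.12% and 1.78%). Cluster 34, led by Cd209a, held 0.697% (0.146%, 0.492%, 0.875% and 1.16%), and cluster 35, led by Mme and Clu, 0.683% (0.292%, 0.0912%, 0.799% and 1.42%). Cluster 39, led by Cspg5, held 0.332% (0.605%, 0.401%, 0.152% and 0.212%) and cluster 44, led by Ccr6, 0.175% (0.417%, 0.182%, 0.0951% and 0.0489%). Cluster 45, led by Ighd and Cd8b1, held 0.148%, with 0, 26, 4 and 2 cells in replicates 1 to 4, so most came from the male library.

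Collagen, immunoglobulin and other genes called with age in 3 or more classes may come from free RNA of other cells. Of the 69 calls of these 18 genes, 56, or 81.2%, were in classes whose level was at or below 10% of that in free RNA, with a change in free RNA of the same direction. Age itself, and differences between preparations that go with age, were not tested apart from this and stay open for the rest.

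A lower share of the cluster led by gamma delta T cell genes may account for part of the T cell genes that were lower with age. Of the 158 lower genes, 130 were not at a level that free RNA could supply, and within cluster 2 alone their median fold was 38.1% of that in all T cells, with 2 still called. For the other 28, such as Col1a1 and Mgp, it was 104.8%, with 12 still called, which argues against that share; 28 of the 28 were lower in free RNA too (median −2.30, against −3.00 in T cells), so free RNA may bring them. Over all 225 genes the median in cluster 2 was 55.7%, between the bounds set for and against the share of clusters. For the 67 higher genes, such as Gzmk and Eomes, the tests did not settle whether that share is the whole cause. Even if cluster 2 alone made their transcripts, its part of T cells could raise them by a log2 fold of 0.53 at most, and their folds had a lower quartile of 1.02 and a median of 1.22, with 55 of the 67 above that limit by more than 2 SE. In cluster 2 alone their median was 78.3% of that in all T cells, with 2 still called and 300 cells of that cluster in the smallest library. A change within cluster 2, or of the mix of cells inside it, stays open for them too. Free RNA is argued against as the whole cause of the T cell calls, since 12.4% of them were at a level it could supply. Age stays an open explanation for the T cell genes, untested.

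Interferon-stimulated genes rose in 5 classes and fell in 3, which free RNA, the male library or a mix of clusters could produce. Of 285 tests of list genes in the 8 called classes, 7, or 2.46%, were at a level that free RNA could supply. Without replicate 2, the male library, 8 of the 8 kept direction and call, and in the largest cluster alone 6 of the 7 classes with more than 1 cluster did, T cells being the exception (0.16). With an estimated correlation between genes none of these list calls passes in camera (lowest adjusted p 0.740), so the tests speak of the calls at the fixed one. They argue against all 3 explanations as the whole cause; a difference between preparations that goes with age was not tested and stays open beside age, so that age acting in different directions in different classes remains a hypothesis.

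Other splits of the 4 libraries into 2 and 2 number 3 with the real one, too few for a share under 0.05. Genes called in the real split and in the highest of the others were 225 and 0 in T cells, 117 and 0 in blood endothelial cells, 36 and 0 in macrophages, 23 and 0 in type 2 innate lymphoid cells, 22 and 0 in neutrophils, 21 and 3 in conventional dendritic cells, 15 and 2 in fibroblasts, 5 and 4 in natural killer cells, 3 and 0 in B cells, and 1 and 1 in monocytes (edgeR).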

How the results depend on the processing

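The mitochondrial limit of 20%, the largest cluster of each class alone, and unnamed clusters counted as fibroblasts are settings chosen only after the result was seen. No paired analysis was possible because each pool of mice belongs to 1 age and the labels tie no library of 1 age to a library of another. B cells and fibroblasts had too few cells for the age test at 5% mitochondrial UMIs, and 13 of 20 classes could be fitted by class there. The largest cluster alone changes nothing in type 2 innate lymphoid cells and natural killer cells, which were 1 cluster each. Except where the setting tests fewer cells, genes or libraries, the cause was not tested.

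Of the 83 genes named with age, none changed direction in any setting, and 83 passed with no filter on low counts, 81 with RLE scaling, 80 at a resolution 2 times as high, 72 by DESeq2, 51 of 75 at 5% mitochondrial UMIs, 58 of 81 in the largest clusters and 35 of 39 without genes that free RNA could supply. Calls were 47.6% higher with age in all, 62.9% in the largest clusters, 59.4%, 61.5% and 62.4% without replicates 1, 3 and 4.

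The T cell count of 225 became 54 at 5% mitochondrial UMIs, 647 with no filter, 119 with equal cells and 16 in the largest cluster, and 0 to 804 without 1 library. The macrophage count of 36 became 21 with lower minimums, 14 and 17 at 5% and 20% mitochondrial UMIs, 20 with list genes in clustering, 379 with no filter, 17 without genes that free RNA could supply and 16 with equal cells, and 53 to 90 without 1 library. The neutrophil count of 22 became 42 at 20%, 50 with doublets, 41 with list genes in clustering, 121 with no filter and 2 without genes that free RNA could supply, and 0 to 131 without 1 library. Over all classes 468 became 238 at 5%, 3133 with no filter and 299 in the largest clusters, and 428 to 1796 without 1 library. Each 0 is edgeR without replicate 4, with 792 and 197 genes at an unadjusted p under 0.05.

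Of 73 lists called, 0 were with an estimated correlation (8 at an unadjusted p under 0.05, lowest adjusted p 0.740), 38 kept call and direction in each fit without 1 library, and 68 to 95 were called in those. The T cell and macrophage difference of 110 became 176 with lower minimums, 66 at 5%, 234 with no filter, 35 in the largest clusters and 69 to 173 without 1 library; T cell and neutrophil, 30, became 115 with higher minimums, 50 at 20%, 53 with doublets, 86 with no filter and 3 to 152; macrophage and neutrophil, 20, became 107, 31 at 20%, 54 with no filter, 53 in the largest clusters and 0 to 94 (366 at an unadjusted p under 0.05 without replicate 4). Called shares numbered 1 in place of 0 among immune cells alone (plasma cells, 2.78). Leaving out 1 library gave fibroblast shares of −3.25 to −1.97 and plasma cells of 2.36 to 4.23. The 5641 class calls became 3232 at 5% and 5258 to 5449 without 1 library.

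With no library block the class count was 5445 in place of 5641.

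The sign changed for H2-Aa in B cells in the largest cluster (−0.014), Iglc1 in monocytes with doublets (−0.0077), MHC class II in fibroblasts at 20% (0.039, by the test's direction) and matrix proteases in neutrophils with equal cells (0.12). Without 1 library it changed for MHC class II in blood endothelial cells (0.033 to 1.51, by the test's direction at the lower end) and monocytes (−1.22 to 0.48), MHC class I in blood endothelial cells (−0.019 to 0.57), and immediate early genes in T cells (−0.14 to 0.45), neutrophils (−0.10 to 0.55), conventional dendritic cells (−0.51 to 0.13) and macrophages (−0.55 to 0.029). The median alone changed sign, where the call was lost or the test kept its direction, for oxidative phosphorylation in B cells (0.039 without 2), the senescence list in neutrophils (0.037 without 4, 0.13 with higher minimums), the list of chemokines, fibroblast (−0.066 with higher minimums, −0.32 with equal cells) and matrix proteases in neutrophils (0.087 and 0.025 without 3 and 4, 0.017 with lower minimums and with doublets, 0.14 with higher minimums).

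Shares that changed sign, none of them called, were Schwann cells (−0.036 with lower minimums, −0.074 with doublets), erythroid cells (0.31 with higher minimums), mast cells or basophils (0.074), osteoblasts (0.073), pinealocytes (−0.28) and plasmacytoid dendritic cells (0.26) at 5%, and pericytes among non-immune cells (0.33). Without 1 library the range held both signs for B cell progenitors (−1.12 to 1.33), Schwann cells (−0.60 to 0.47), T cells (−0.16 to 0.78), erythroid cells (−0.79 to 0.83), pericytes (−0.53 to 0.076) and plasmacytoid dendritic cells (−0.68 to 0.051).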

Other observations

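Several lists moved with age in 1 to 4 classes in which they have not yet been described. Mitochondrially encoded genes, which complete the respiratory chain, fell in neutrophils of the older libraries (median log2 fold −0.68, 0 of 13 positive, adjusted p 6.08e-07 in camera, and 0.740 with an estimated correlation), with 9 lower adjusted over the list alone, such as mt-Atp6 (−0.77, SE 0.26), and 0 over all genes by edgeR or DESeq2, and in fibroblasts (−0.33, adjusted p 0.0268, and 0.783 with an estimated correlation), where the call was lost without replicates 1 (−0.27) and 3 (−0.27). Without replicate 2 the fibroblast median was −0.54, and without replicate 4 the neutrophil one was −0.39. A median of 3.55% and 3.72% of UMIs per cell were mitochondrial in the older libraries and 5.24% and 4.92% at 2 months, where more barcodes exceeded the mitochondrial limit (29.2% and 28.6%, against 16.8% and 13.6%), so cell quality is not set apart from age in this fall. Haemoglobin genes fell in T cells (−1.79, adjusted p 0.0213, and 0.740 with an estimated correlation), with Hba-a1 at −1.98 (SE 0.36), Hba-a2 at −1.88 (SE 0.35) and Hbb-bs at −1.79 (SE 0.36) called over all genes by edgeR (0 by DESeq2), and were not called without replicate 3 (−1.09). In free RNA, haemoglobin genes had a median log2 fold of 0.32.

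Immediate early genes, which respond to stress and to tissue digestion, rose in neutrophils (median log2 fold 0.30, adjusted p 0.0218) and T cells (0.16, adjusted p 0.0398), and fell in conventional dendritic cells (−0.23, adjusted p 0.0233) and macrophages (−0.23, adjusted p 0.0213); with an estimated correlation the adjusted p was 0.853 to 0.880. In T cells 0 members passed over all genes by edgeR or DESeq2 (3 higher at an unadjusted p under 0.05), with Ier3 at 1.97 (SE 0.44, adjusted p 0.0572, and 0.0372 over the list alone). None of these 4 calls passed in each fit without 1 library: the medians without the library that turned them were −0.10 in neutrophils and −0.14 in T cells (replicate 2), 0.021 and 0.13 in dendritic cells (replicates 1 and 3) and 0.029 in macrophages (replicate 3), and the calls also ended in neutrophils (0.18) and T cells (−0.088) without replicate 4 and in macrophages without replicate 1 (−0.24). Without replicate 1 the median was 0.55 in neutrophils and 0.45 in T cells, and without replicate 3 it was 0.40 in T cells. Without replicates 2 and 4 it was −0.48 and −0.51 in dendritic cells and −0.36 and −0.55 in macrophages. Genes of the senescence list fell in B cells (−0.25, adjusted p 0.00163), neutrophils (−0.054, adjusted p 0.0221) and natural killer cells (−0.26, adjusted p 0.0346), each with Igfbp5 as the member called over all genes, at a level that free RNA could supply, and with an adjusted p of 0.740 with an estimated correlation. That call was lost in B cells without replicates 2 (−0.14) and 3 (−0.11) and in neutrophils without replicates 1 (−0.42) and 4 (0.037). The median was −0.73 and −0.38 in B cells without replicates 1 and 4, −0.32 and −0.29 in neutrophils without 2 and 3, and −0.61, −0.82, −0.40 and −0.61 in natural killer cells without 1 to 4. Matrix proteases and their inhibitors fell in blood endothelial cells (−0.41, adjusted p 0.0372) and in neutrophils (−0.0075, adjusted p 0.0218), with an adjusted p of 0.740 with an estimated correlation, and heat shock genes fell in monocytes (−0.25, adjusted p 0.00182, and 0.742 with an estimated correlation). In endothelial cells 0 protease genes passed over all genes by edgeR or DESeq2 (1 higher and 5 lower at an unadjusted p under 0.05), with Mmp14 at −1.28 (SE 0.30, adjusted p 0.0827, and 0.0284 over the list alone). The protease call was lost in endothelial cells without each library in turn (−0.44 to −0.12) and in neutrophils without replicate 3 (0.087; −0.28, −0.041 and 0.025 without 1, 2 and 4), and the heat shock call in monocytes without replicates 1 (−0.11) and 4 (−0.11), with −0.49 without replicate 2. In free RNA the medians were −0.42 for mitochondrially encoded genes, 0.16 for immediate early genes, −0.28 for the senescence list and −0.66 for matrix proteases. Lipid handling genes passed in 0 of 10 classes with camera.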
